A study of Rattus norvegicus with 35 samples.

How the data were processed

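The series measured messenger RNA in rat converted hypoblast stem cells. These cells were derived from rat embryonic stem cells in medium with LIF, PDGF, EGF and serum, and were collected on day 12 of differentiation. Per the labels' protocols, RNA was prepared with the C1 Single-Cell Auto Prep kit, a microfluidic system that isolates single cells in chambers, and libraries were made with the Nextera XT protocol. The labels describe 34 libraries as single cells and 1 library as a bulk population control. No culture number, passage or batch is given, so the cells were treated as 1 sample and the bulk library as another.

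The values used are whole-number read counts per transcript record, as deposited by the authors in 1 table with a column for each library. Per the submitters' processing notes, TopHat2 and the rn5 build were used. The read counter and the gene annotation are not given in the sources used here, and neither is the handling of reads that map to several genes. No molecular identifiers are mentioned in the labels, so amplified copies of 1 molecule count as several reads. Even counts made up 59.8% to 72.6% of the nonzero counts in the cells and 79.9% in the bulk library, an excess of even counts that independent reads would not give. The intervals and floors given cover the counting error of independent reads only, so intervals are too narrow and floors too low. Intervals of ratios take the bulk reads alone and hold the cells' mean fixed, except for Cck. The table held 17201 records, of which 16215 were matched by identifier to a gene symbol in a RefSeq gene table. The other 986 records held 4.11% of the reads and kept their identifiers. They stayed in the library totals.

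Total reads in genes ranged from 6288 to 503044 in the cells (median 266046) and were 47121 in the bulk library. A single read was therefore worth 21.2 CPM, the count scaled by the total of its library, in the bulk library and between 1.99 and 159 CPM in a cell. A count of 0 in the bulk library allows up to 3 reads, or 63.7 CPM. Where a gene had no bulk read, the fold is a lower bound against that floor, for independent reads. No fold is given when the cells' mean was at or under the bulk floor as well. The cells were compared with one another for copies of 1 library: none of the 561 pairs held identical counts, and Pearson's r of log2(CPM + 1) across genes, which are not independent replicates, lay between 0.18 and 0.70.

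Counts were scaled to CPM by library totals. The cells' level of a gene is the mean CPM of the 34 cells, each weighted equally, and the SD is the spread between cells. A gene was called detected in a cell at 5 CPM or more, with exact Clopper-Pearson 95% intervals for shares of cells and exact Poisson 95% intervals for reads. Each group is 1 sample, so no test across samples exists and no p-value, standard error or number of changed genes is given. No doublet caller was run on the 34 chambers, and no cell was removed from the main results.

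Cells and bulk were compared on log2(CPM + 1) over genes with a mean of both levels of at least 1 CPM. Spearman's rho was computed for all cells, each cell alone and 100 random pools each of 2, 5, 10 and 20 cells. For each of 19 gene lists, the median log2 ratio was placed among 10000 random lists of the same size, matched in 10 bins of mean expression. Lists outside the central 95% of random lists are said to stand apart, as a description of these libraries. Spread between cells was measured as the squared coefficient of variation of CPM in excess of a lowess trend (fraction 0.3) on mean expression. Co-detection of pluripotency and hypoblast genes was set beside the number of cells that independent detection would give. Cells were clustered by Ward's method on the 500 genes with the highest excess spread and a mean of at least 10 CPM. The number of clusters, from 2 to 6, was the one with the highest mean silhouette width, which was set beside 100 tables with every gene shuffled over cells.

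The gene lists, the comparisons and the rule for named genes were fixed before the data were examined. The lists covered core hypoblast, basement membrane, parietal endoderm, visceral endoderm, pluripotency, postimplantation epiblast, trophoblast, primitive streak with mesoderm and definitive endoderm, neural and fibroblast genes. They also covered the LIF pathway, the PDGF, EGF and FGF pathways, S phase, G2/M phase, immediate early and stress genes, glycolysis, epithelial state, blood and housekeeping genes. The rule named a set of key lineage genes and the 4 members of each list with the highest mean CPM over cells. It also named the 10 genes with the highest mean CPM. For cells over bulk, it named the 10 largest log2 ratios among genes with a cells' mean of at least 20 CPM that were detected in at least 17 cells. For bulk over cells, it named the 10 largest among genes with at least 20 CPM in bulk. For spread, it named the 10 genes with the largest excess among those with a mean of at least 50 CPM and detection in at least 4 cells. A few genes that this rule names are not reported here. Other genes named in the text were chosen after their values were seen. Zfp42, a key gene by that rule, was not matched to a record. Cluster names were allowed only from the fixed lists, and the clusters are left unnamed.

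Alternatives tried were TMM factors from edgeR and poscounts size factors from DESeq2 in place of totals, reads pooled over cells, the median over cells, pseudocounts of 0.1 and 10 CPM, all genes with a read and a minimum mean of 10 CPM. Detection was also read at 1 count and at 50 CPM. Reads were also thinned to 61770 per cell, which left out 4 shallower cells. A filter on cells more than 3 median absolute deviations below the median in reads or genes kept 25 cells. Spread was also measured as the SD of log2(CPM + 1), and clusters were recomputed with 200 and 1000 genes, average linkage, and without the cell cycle lists. A pair of alternatives was chosen after seeing the data: totals without Rn45s, the ribosomal RNA precursor, and the cells without those holding Col1a2 at 5 CPM or more.

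The list procedures were tested on simulated data. For cells against bulk, over 8327 genes, 20 of 20 lists raised 4-fold and 16 of 20 lists lowered 4-fold were recovered. These altered lists held 5 genes each. Of 100 unchanged lists of 10 genes each, 2 stood apart. For spread between cells, over 8893 genes, 20 of 20 lists of 10 genes each were recovered. These rates describe the simulated lists and may not carry over to the fixed lists, which differ in how many genes lack a bulk read. Among the genes compared, 6 of 11 pluripotency, 2 of 10 fibroblast and 0 of 13 basement membrane genes had no bulk read. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.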

Results

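The transcriptomes of 34 single rat converted hypoblast stem cells and 1 bulk population library were profiled on day 12 of differentiation. The hypoblast, or primitive endoderm, is the layer of the early embryo that gives rise to the parietal and visceral endoderm of the yolk sac. Cells held 237060 ± 139833 reads in genes (mean ± SD over 34 cells) and between 349 and 5514 genes with a read, with a median of 4306. The bulk library held 47121 reads and 4741 genes. The cell labelled C94 was the shallowest, with 6288 reads, followed by C88, with 12750 reads. Cells are referred to by their labels. SDs describe cells, which are not replicate cultures, and with 1 sample per group no difference could be tested.

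**Figure D1:**
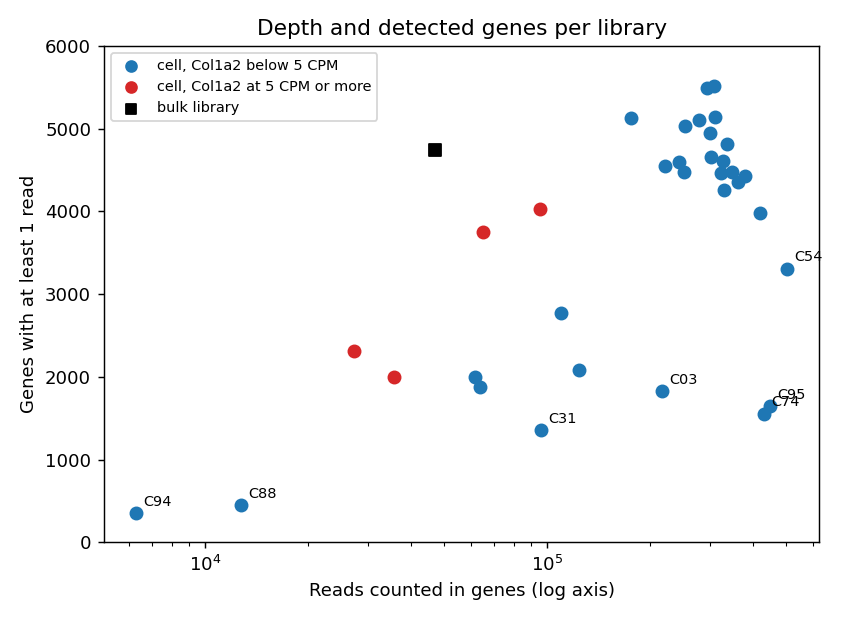
Reads counted in genes (x axis, log scale) and genes with at least 1 read (y axis) for each of the 34 cells (circles) and the bulk library (square), with red circles for cells with Col1a2 at 5 CPM or more. The bulk library held 47121 reads, fewer than most cells, and 4741 genes.

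The first question was which lineage genes the cells expressed. Most cells expressed the core transcription factors of the hypoblast. Gata6 was detected in 28 of 34 cells (82.4%, interval 65.5% to 93.2%) at 346 ± 569 CPM, Gata4 in 26 cells at 258 ± 310 CPM and Sox17 in 24 cells. Dab2, an endocytic adaptor of extraembryonic endoderm, was detected in 27 cells at 365 ± 458 CPM, and Pdgfra, the PDGF receptor that marks the primitive endoderm, in 23 cells at 182 ± 287 CPM. Foxa2 was detected in 19 cells, Sox7 in 12 and Hnf4a in 1. Of the 16 measured core hypoblast genes, 7 were detected in at least 17 cells and 2 in none. The mean of Sox17, 399 CPM, rested on C88, which held 86.8% of the signal, and was 54.3 CPM without that cell. At a threshold of 50 CPM, Sox17 was detected in 11 cells, Pdgfra in 15 and Gata6 in 25.

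Basement membrane genes were among the most abundant and most widely detected lineage genes. Lama1 (3163 ± 3837 CPM, 30 cells) and Lamc1 (2428 ± 2211 CPM, 30 cells) encode laminin chains, and Col4a1 (1591 ± 1237 CPM, 32 cells) encodes a type IV collagen chain. Sparc, a matrix glycoprotein, was detected in 33 cells at 2907 ± 2210 CPM. In all, 10 of the 14 measured genes of this list were detected in at least 17 cells. Of 14 parietal endoderm genes, 5 reached that share, including the cathepsin gene Ctsl (10887 ± 13002 CPM, all 34 cells), the proteoglycan gene Srgn (1559 ± 1536 CPM, 30 cells), Vim (565 ± 936 CPM, 28 cells) and Thbd, which encodes thrombomodulin (20 cells). The mean of Thbd, 795 CPM, was 501 CPM without C94 and still leaned on C31, which held 9003 CPM. The highest Vim values were in C30 (4325 CPM), C14 (2831), C09 (1931), C17 (1830) and C46 (1510). All of these but C09 held Col1a2, a fibroblast list gene, so the mean of Vim leans on those cells.

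Visceral endoderm genes were detected in few cells, with the exception of Apoe (1032 ± 1101 CPM, 26 cells). Of the 21 measured genes of this list, 13 were detected in no cell. Ihh was detected in 5 cells, Apom in 3 and Apoa4 in 1. Ttr, the transthyretin gene, had 0 reads in the cells, and Afp, the alpha-fetoprotein gene, had 1 read. The interval for 0 of 34 cells reaches 10.3%, which limits the share of cells with detection and not the share expressing the gene.

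Pluripotency genes were split between widely and rarely detected members. Klf4, Klf5 and Lin28a were each detected in 29 cells, at means of 333, 821 and 429 CPM. A single cell held 56.1% of the Klf4 signal (C88) and 74.6% of the Klf5 signal (C94), and the means without these cells were 151 and 215 CPM. Pou5f1, which encodes the pluripotency factor Oct4, was detected in 3 cells (8.82%, interval 1.86% to 23.7%) and had 0 reads in bulk. Of its 527 reads in the cells, 505 were in C74. Sox2 was detected in 3 cells with 7 reads in all, and Nanog in 7 cells with 15 reads. Dppa3 was detected in 6 cells. Of the 14 measured pluripotency genes, 3 were detected in at least 17 cells and 3 in none.

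Most genes of other lineages were detected in few cells or none. Of 13 streak, mesoderm and definitive endoderm genes, 12 were detected in no cell, among them Tbxt with 0 reads, and Mixl1 was detected in 4 cells. Cdx2, a trophoblast factor, also had 0 reads. Keratin genes Krt18 (433 ± 701 CPM, 26 cells) and Krt8 (230 ± 440 CPM, 23 cells) were the 2 trophoblast list members found in at least 17 cells, and both also belong to the epithelial list. Plac1 was detected in 4 cells and Tfap2c in 6. On the neural list, Tubb3 was detected in 27 cells, Nes in 8 and Gfap in 2. Of 7 postimplantation epiblast genes, only Cldn6 (21 cells) reached 17 cells, while Dnmt3a was detected in 8, Zic2 in 3 and Pim2 in 1. Gata1 was the 1 blood list gene detected, in 7 cells, and the haemoglobin genes had 0 reads. Of 13 fibroblast genes, Acta2, which encodes smooth muscle actin, was detected in 32 cells, Tagln in 8, S100a4 in 5 and Col1a2 in 4.

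Many S phase and glycolysis genes were detected in most cells, and fewer G2/M genes were. Of 21 S phase genes, 13 were detected in at least 17 cells, led by Rrm2, a subunit of ribonucleotide reductase (1460 ± 1601 CPM, 31 cells), Pcna (25 cells), Mcm6 (21) and Hells (21). For G2/M phase the number was 8 of 20, with Ccnb1 in 23 cells, Kif23 in 19, Mki67 in 18 and Cdc20 in 16. For glycolysis it was 11 of 15, including Ldha (1360 ± 1124 CPM, 30 cells), Aldoa (1272 ± 822 CPM, 31 cells), Pkm (899 ± 946 CPM, 31 cells) and Gapdh (894 ± 746 CPM, 32 cells). LIF pathway genes Ptpn11 and Stat3 were each detected in 24 cells, Il6st in 15 and Lifr in 13. In the PDGF, EGF and FGF pathway list, 2 of 16 genes reached 17 cells, Pdgfra and Spry2 (18 cells). Dusp6 was detected in 10 cells and Phlda1 in 7. Among immediate early and stress genes, Hsp90aa1 was detected in all 34 cells, Fos in 18, Atf3 in 16 and Ddit3 in 13. Records with the highest means included Rn45s, Actb, Hsp90ab1, Ctsl, Ubb, Eef1a1, Ripor2, Actg1 and 1 record without a matched symbol. Rplp0, a ribosomal protein gene on the housekeeping list, was detected in all 34 cells at 5803 ± 3585 CPM.

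**Figure D2:**
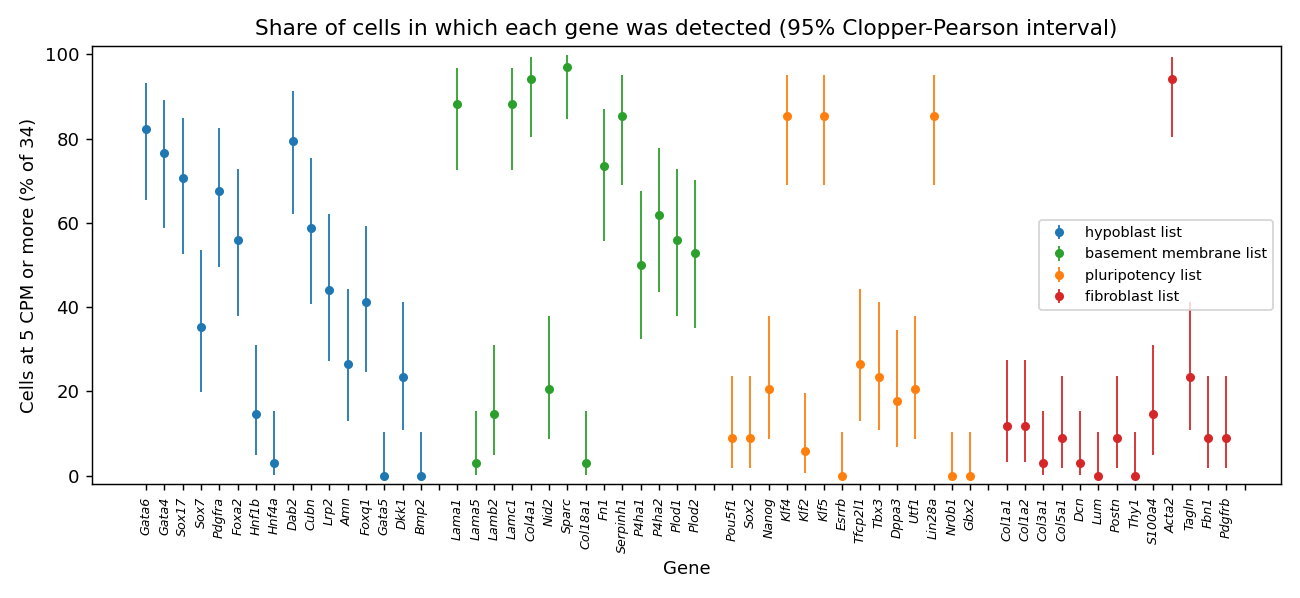
Share of the 34 cells with each gene at 5 CPM or more (y axis, percent) for genes of the hypoblast, basement membrane, pluripotency and fibroblast lists (x axis, coloured by list). Bars are exact Clopper-Pearson 95% intervals for counting error. Sparc, detected in 33 cells, has the highest share and Pou5f1 and Sox2 were each detected in 3.

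The next question was whether hypoblast and pluripotency transcripts occurred in the same cells. Pou5f1, Nanog, Sox2 and Klf4 were each paired with Gata6, Gata4, Sox17, Sox7, Pdgfra and Foxa2, giving 24 pairs. All 24 pairs were detected together in at least 1 cell. Of these, 10 pairs were found in more cells than independent detection would give and the rest in fewer. Klf4 was detected in 29 cells, so its pairs had to overlap. The expected numbers also ignore that cells held from 349 to 5514 genes with a read, which by itself raises co-detection. The 3 cells with Pou5f1 all had Gata4, where 2.29 were expected. Nanog and Gata6 were found together in 6 cells, against 5.76 expected, and Klf4 and Gata6 in 26 cells, against 23.9. Below expectation were Pou5f1 and Gata6 (2 cells, against 2.47), Nanog and Foxa2 (3, against 3.91) and every Sox2 pair, such as Sox2 and Sox17 (1, against 2.12). At 50 CPM, 10 of the 24 pairs occurred in any cell, none of them with Nanog or Sox2. Nanog was detected in 0 cells at that threshold and Sox2 in 1, so no Nanog pair could occur. After thinning, 16 of the 24 pairs occurred in any cell and 8 in more cells than expected, with Sox2 then detected in 0 cells. Other settings went the other way. At 1 read, 13 pairs exceeded expectation, among them Nanog and Foxa2 (7 cells, against 6.15). For the 25 cells kept by the depth filter the number was also 13. Without the cells with Col1a2, an alternative chosen after the results were seen, it was 12. Cells of 1 culture are not independent samples, and these counts carry no test.

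The bulk library served as a population control for the single cells. Across 9023 genes, Spearman's rho between the mean of the cells and the bulk library was 0.551 and Pearson's r was 0.529. These are correlations across genes, which are not independent replicates. A single cell reached a rho of 0.134 (C94) to 0.464 (C27) with the bulk, with a median of 0.395. The median rho rose with the number of cells pooled, to 0.443 for 2 cells, 0.489 for 5, 0.518 for 10 and 0.538 for 20. Each cell's rho with the mean of the other cells was 0.175 to 0.636, with a median of 0.564. With the median over cells in place of the mean, the rho with bulk was 0.339. Of the genes, 4650 had a read in both, 6043 in the cells alone and 91 in the bulk alone.

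**Figure D3:**
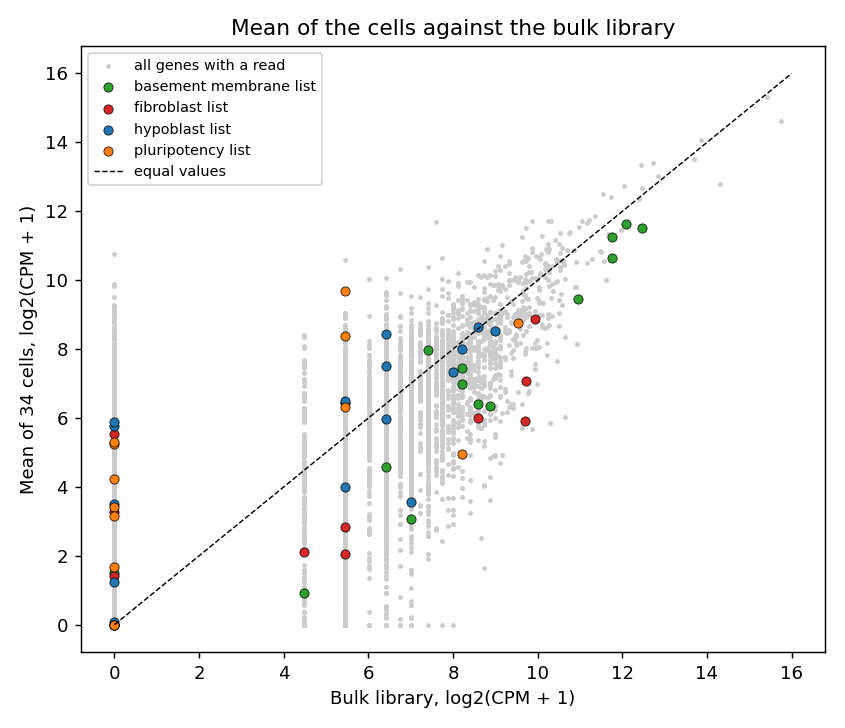
Mean of the 34 cells against the bulk library, both as log2(CPM + 1), for all genes with a read (grey) and for genes of 4 lists (coloured); the dashed line marks equal values. Vertical bands at the left are genes with 0 to a few bulk reads, each bulk read being worth 21.2 CPM, and most basement membrane genes lie below the line.

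Matrix genes had higher levels in the bulk library than in the mean of the cells. Of 13 basement membrane genes compared, 12 were higher in bulk, and the list's median log2 ratio of cells to bulk was −1.24, at percentile 0.375 of random lists. Col4a1 was 3480 CPM in bulk, 2.19-fold the cells' mean (interval 1.87 to 2.55), Sparc 1.93-fold (1.71 to 2.18), Lamc1 1.42-fold (1.21 to 1.65) and Lama1 1.37-fold (1.19 to 1.57). The fibroblast list had a median of −2.47, at percentile 0.01, with 7 of 10 genes higher in bulk. Col1a1 was 14.1-fold higher in bulk (interval 10.02 to 19.3, 39 bulk reads) and Col1a2 was 6.29-fold higher (4.49 to 8.56, 40 bulk reads). These ratios depended on 1 cell each, being 27.6-fold for Col1a1 without C14 and 11.4-fold for Col1a2 without C30. Core hypoblast genes had a median of 0.06, at percentile 53.9. Gata4 in bulk was 1.15-fold the cells' mean (interval 0.631 to 1.94), and Gata6 was 4.08-fold higher in the cells (1.59 to 14.98, 4 bulk reads).

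Pluripotency genes stood apart in the other direction, with a median of 3.14 at percentile 99.2. Of the 11 genes compared, 6 had no bulk read, so the size of this median depended on the pseudocount. It was 4.51 with a pseudocount of 0.1 CPM and 0.98 with 10 CPM. The list did not stand apart with a pseudocount of 0.1 CPM (percentile 22.3), with a pseudocount of 10 CPM (93.6), with TMM factors (89.8), with the median over cells (41.9) or without the 9 shallow or gene-poor cells (83.0). Without those 9 cells, trophoblast (0.36) and G2/M genes (1.42) stood apart as higher in bulk. With all cells no other list did, with percentiles of 47.8 for parietal endoderm, 45.6 for visceral endoderm, 28.9 for postimplantation epiblast, 20.3 for trophoblast and 76.4 for neural genes. They were 42.7 for the LIF pathway, 4.27 for the PDGF, EGF and FGF pathways, 30.045 for S phase, 6.88 for G2/M phase, 86.1 for stress, 51.6 for glycolysis, 61.1 for epithelial and 70.1 for housekeeping genes. The streak and blood lists each had 1 gene with enough reads and were not placed. The median log2 ratio over all genes was 1.61, with many genes lacking a bulk read, and it was −0.01 over genes with a mean of at least 10 CPM.

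The largest ratios in favour of the cells were all of genes without a bulk read. Elovl6, a fatty acid elongase gene, was detected in 25 cells at 470 ± 551 CPM, at least 7.39-fold above the floor of 3 bulk reads, which takes reads as independent. For 8 other genes (Ahctf1, Fbxo11, Pawr, Hdac2, B3gat3, Sfpq, Mrpl45 and Phf14), 1 cell each held 61.0% to 89.9% of the signal. In favour of the bulk, Cck had 20 bulk reads and 2 reads in the cells, both in C30, a ratio of 197 (interval 47.8 to 1737, from the reads of both). Prl3d1, a placental lactogen gene, had 12 bulk reads, Lcp1 10, Mmp1 8, Dlx3 and Fndc3c1 6 each, and Tns4 and Rab40c 5 each, all with 0 reads in the cells. Erbb3 and Tns1 had 6 bulk reads each, with 1 and 2 reads in the cells.

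The last question was how far the cells differed from one another. The lists of fibroblast (percentile 100 of random lists), pluripotency (99.8), parietal endoderm (98.5) and epithelial genes (98.1) had more spread between cells than matched random lists. Core hypoblast genes were at percentile 89 and basement membrane genes at 66.8. The other lists lay at 79.2 for visceral endoderm, 88.5 for postimplantation epiblast, 96.5 for trophoblast, 16.1 for neural genes, 25.2 for the LIF pathway and 65.3 for the PDGF, EGF and FGF pathways. S phase was at 35.8, G2/M phase at 89.4, stress at 91.3, glycolysis at 29.6 and housekeeping at 8.33. Measured as the SD of log2(CPM + 1), fibroblast and pluripotency genes instead had less spread than random lists, at percentiles 0.82 and 0.255. With that measure housekeeping genes were also low (0.05), S phase (99.5) and G2/M genes (99.98) were high and parietal genes did not stand apart (75.9). With size factors the parietal (95.8) and epithelial lists (90.8) no longer stood apart, and without the 9 shallow or gene-poor cells the pluripotency list did not (87.5) while the trophoblast list did (99.9). After thinning the parietal list did not stand apart (93.9) and the trophoblast list did (99.6). Without the 4 cells with Col1a2, an alternative chosen after the results were seen, the parietal (84.5) and epithelial lists (95.3) did not, while the stress list narrowly did (97.505). The 10 genes with the largest excess spread (Fscn3, Prickle1, Pabpc1, Uqcc3, Rbbp8, Frmd8, Lpar3, Zdhhc7, Sdhc and Pla2r1) each drew 78.7% to 99.8% of their signal from 1 cell, which was C94, C88 or C03.

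Clustering gave 2 clusters of 24 and 10 cells, with a mean silhouette width of 0.105, against at most 0.0486 in 100 shuffled tables. Shuffling every gene also removes differences in depth between cells, and the clusters had median reads of 296706 and 64371. The shuffled tables therefore cannot tell cell states from library quality. The smaller cluster held C94 and C88, the shallowest cells, C54, the deepest, the 4 cells with Col1a2 (C14, C17, C30 and C46), and C09, C74 and C95, with few genes. C03 and C31, also with few genes, were in the larger. The clusterings under other settings differed from this one: the adjusted Rand index with it was 0.767 for 200 genes, 0.530 for 1000 genes, 0.606 without the cell cycle lists, 0.0807 for average linkage, 0.360 after thinning and −0.09 for the 25 cells kept by the depth filter. The clusters were not named, and no gene is reported as marking them.

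**Figure D4:**
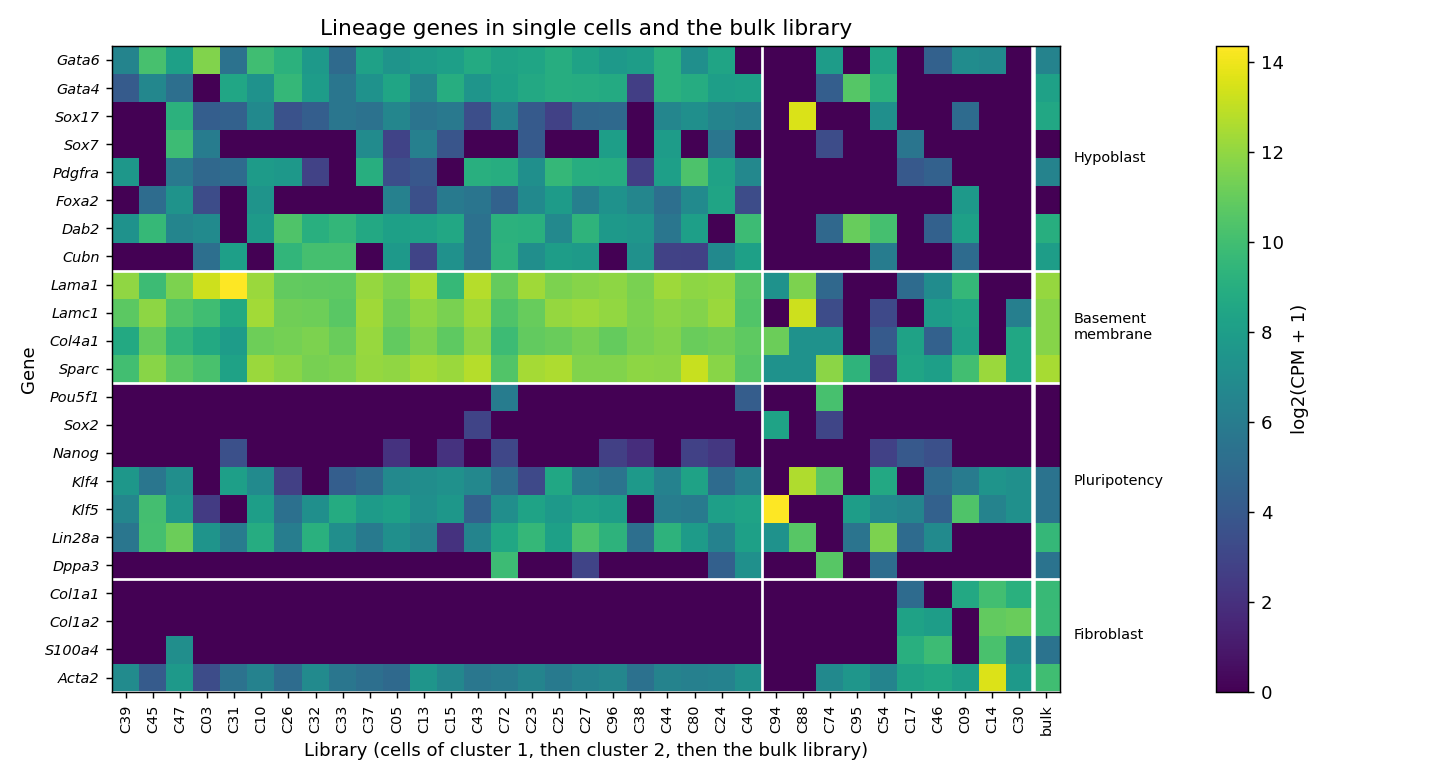
Levels of selected hypoblast, basement membrane, pluripotency and fibroblast genes (y axis) in the 34 cells and the bulk library (x axis), coloured by log2(CPM + 1). The vertical lines separate the clusters of 24 and 10 cells and the bulk library; Col1a2 is above 0 in 4 cells and in bulk, and Pou5f1 in 3 cells.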

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

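The alternatives of totals without Rn45s and of leaving out the cells with Col1a2 were chosen after the results were seen. The agreement of cells and bulk fell from a rho of 0.551 to 0.339 with the median over cells and to 0.392 over genes with a mean of at least 10 CPM, which drops the low genes. The median share of cells with a hypoblast gene fell from 42.6% to 23.5% at 50 CPM. With size factors, 2 lists in place of 4 stood apart in spread. The best number of clusters was 6 in place of 2 with 1000 genes, without the cell cycle lists, and after thinning, and the cause was not tested. The pluripotency list's ratio of cells to bulk turned to −2.42 with the median over cells, where the median over all genes also turned, from 1.61 to −3.53. With a pseudocount of 0.1 CPM the list's median was 4.51 but its percentile fell to the other side of the middle. Fibroblast and pluripotency genes went from high to low spread (percentiles 0.82 and 0.255) with the SD of log2(CPM + 1). The cause was not tested. The fibroblast list stayed at or under percentile 2.12 and the basement membrane list at or under 1.25 in cells against bulk under every alternative run. However, their median log2 ratios ran from −5.44 to −1.46 and from −3.73 to −0.53. Both low ends came from the median over cells, where the median over all genes was −3.53. Of the other main results, 41 comparisons with an alternative lay within a tolerance of the main value. For clusters and lists standing apart this compares counts, not members. With average linkage the 2 clusters held 33 and 1 cells. Of the comparisons of single gene and list values, 276 lay within their tolerance, 65 went beyond it and 4 changed side. These counts do not measure closeness, since the tolerance differed between lists. The basement membrane ratio of −3.73 with the median over cells, against −1.24, counted as within it. The PDGF, EGF and FGF pathway ratio of 1.818 with size factors, against 1.819, counted as beyond it. No paired analysis was possible because the bulk library is 1 sample and no cell shares a culture number with it. The 47121 reads of the bulk library limit what it can show: genes under 63.7 CPM can be missed there.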

Other observations

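The tests of low depth, 2 cells in a chamber, another species and carry-over were chosen after the results they measure had been seen; the others were set down before their values were seen, on patterns already noticed. The ranges over resampled genes for the trophoblast and Pou5f1 tests were added after their values were seen.

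Further genes with higher levels in bulk, or of cell adhesion, were picked after their values were seen. Plac1, a placental gene, had 26 bulk reads and was 9.30-fold higher in bulk (interval 6.08 to 13.6) or 15.5-fold without C40, while 4 cells held it. Tbx3 was 9.89-fold higher in bulk (5.41 to 16.6) and Slc2a3, a glucose transporter gene, 8.11-fold (5.98 to 10.7) or 12.6-fold without C72. Apoe was 3.02-fold higher in bulk (2.55 to 3.55), and Fn1, the fibronectin gene, 2.85-fold (2.31 to 3.49). Cdh1, the E-cadherin gene, was detected in 21 cells and Epcam in 15.

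Col1a2 was detected in 4 cells, C14, C17, C30 and C46, at 1906, 308, 2126 and 252 CPM, and Gata4, Sox17 and Cubn were detected in none of them, against 3.06, 2.82 and 2.35 cells expected, Dab2 in 1 (3.18 expected), Gata6 and Pdgfra in 2 each (3.29 and 2.71), Lama1 and Lamc1 in 2 each (3.53), Col4a1 in 3 (3.76) and Sparc in all 4. On a second list of 24 mesenchymal genes that shares none with the lists above, 3 of the 4 were among the 4 highest cells (0.471 expected by chance), C46 ranked 5 and C47, without Col1a2, ranked 3; 7 of these genes were detected in at least 50% of the other cells. After thinning to 27284 reads, which left out C88 and C94, the best of the 4 held 2 of 8 hypoblast and laminin genes. Of 28 other cells, 3.57% (1 cell, C95, with 1642 genes before thinning) held as few. This argues against read depth alone. Thinning of reads cannot show what a gene-poor library would give, so that stays open for these 4 cells. The highest sum of Lama1 and Lamc1 among them was 6.39% of the median of the other cells, which argues against a hypoblast cell in all 4 chambers but not in a single one, since 4 of the 30 other cells were lower, among them C54, with Gata4 at 573 CPM. Cells of a mesenchymal type in the culture are a candidate explanation, and the labels name none. Cells of another species, whose reads may align poorly, stay open, since the highest total of the 4 was 32.1% of the median of the others. The separation was less complete with other fibroblast genes. Of the 4 cells with Col1a1, none had Gata4, while Sox17 and Cubn were each in 1 (2.82 and 2.35 expected). Of the 5 cells with S100a4, none had Cubn, while Gata4 was in 1 (3.82 expected) and Gata6 and Pdgfra in 3 each (4.12 and 3.38). C09 held Col1a1 at 408 CPM with Lama1 at 738 CPM, and C46 had no Col1a1 read.

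Prl3d1 and Dlx3, placental genes, had bulk reads and none in the cells. Trophoblast-type cells present in the bulk culture and missed by the 34 chambers might give this. On a second list of trophoblast genes, the 11 with enough reads had a median log2 ratio of cells to bulk of 2.06, at percentile 42.4 of matched random lists. This was above the limit of 25 set beforehand to count against the explanation, but not by more than its range over resampled genes (17.9 to 95.6), and 8 of the 11 genes had no bulk read. Of the 33 measured genes, 3 had a bulk read, and the test decides neither for nor against trophoblast-type cells.

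C74 held 505 Pou5f1 reads (1170 CPM), 18.1 times the CPM of the next cell, C72, and all other libraries together held 22; carry-over from libraries not analysed here could not be tested. A cell with a wider pluripotency programme might explain it, and genes of the first list went both ways in C74: Dppa3 was higher than in any other cell (1564 CPM), Klf4 (1624 CPM) and Tfcp2l1 (461 CPM) were second highest, and Lin28a, Klf5 and Nanog had 0 reads. On a second list of 13 measured pluripotency genes, C74 ranked 23 of 34, which gives it no support, being past the limit of 17 set beforehand, but it ran from 5 to 32 over resampled genes and leaves it open, and C74 held only 1556 genes with a read. Compared with random genes within the same cell, the second list was at percentile 50.3 in C74. The other cells with Pou5f1, C72 and C40, ranked 1 and 2 on it, at percentiles 95.8 and 90.4, which was noticed after the test and needs other cells to check it.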
